A study of Mus musculus with 6 samples.

How the data were processed

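RNA was measured by stranded poly(A) RNA sequencing in 6 libraries of primary mouse adipocytes that carry loxP-flanked copies of Ppargc1a. Per the labels, libraries came from a stranded mRNA kit and were read as paired ends on a NovaSeq instrument. The 6 libraries fall into 3 groups of 2: GFP adenovirus with control siRNA, GFP adenovirus with Rbm43 siRNA, and Cre adenovirus with Rbm43 siRNA. Groups and replicate numbers were taken from the sample titles. The design text calls the samples biological duplicates and does not say whether they came from separate animals. Cells given Cre virus and control siRNA were not analysed here.

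The deposited table holds a normalized signal per gene, read counts divided by 1 size factor per library, with 35976 rows. The submitters' processing notes list fastp 0.23.2, STAR 2.7.8, DESeq2 2.11.40.7 and the mm10 build, without roles or order. The gene counter, the annotation and the strand setting of the counting are not given in the sources used here. Every deposited value was a whole multiple of what 1 read was worth in its library, within 0.01 read (100% of values in each library). Size factors recomputed by the median of ratios from the recovered reads differed from the deposited ones by at most 0.0027%. Recovered reads in genes summed to between 15775398 and 21961724 per library, and 1 read was worth 0.878 to 1.217 normalized counts. No row lacked a gene name, 27 rows carried symbols that a spreadsheet had turned into dates, and 4 rows shared 2 repeated symbols.

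Of the 35976 rows, 13032 were at 0 in every library. Genes with a normalized count of at least 10 in at least 2 libraries were tested, 14211 in all. The test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(normalized count + 1), 1 mean per group, all 6 libraries in 1 fit with 3 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. Errors beside log2 fold changes are standard errors (SE) from this fit. The 3 contrasts were Rbm43 siRNA minus control siRNA with GFP virus, Cre virus minus GFP virus with Rbm43 siRNA, and Cre virus with Rbm43 siRNA minus GFP virus with control siRNA. A fit with replicate number as a block, and the check of whether the numbers pair the libraries, are in the closing section.

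Fixed gene lists, 28 in all, covered mitochondrial, adipocyte, immune and stress functions and markers of other cell types. Each list with at least 5 tested members (26 lists, 78 tests with the 3 contrasts) was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 78 tests, and again with an estimated correlation and with fry. No list kept its call with the estimated correlation, where the smallest adjusted p was 0.141. List members were counted as changed at an adjusted p under 0.05 over all genes tested, and again adjusted over the list alone. The lists for lymphocytes, mast cells and neutrophils (2 tested members) and for skeletal muscle (3 tested members) were too short for a test.

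Genes were named by a rule. Rbm43 and Ppargc1a are named in each comparison. Next come the 10 largest rises and the 10 largest falls past the threshold, with a mean normalized count of at least 50, both libraries of one group above both of the other, and a symbol of their own. Up to 4 members with the smallest p come from each list described. The design, the gene lists, the naming rule and the other settings listed below were fixed before the data were examined.

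The procedure was tested on simulated data for the comparison of Rbm43 siRNA with control siRNA (14061 genes). It recovered 53.1% of genes changed 1.25-fold, 71.4% at 1.5-fold, 94.0% at 2-fold and 96.0% at 4-fold, and called 6 of 13863 unchanged genes. All 3 lists shifted by 0.3 on the log2 scale were called at the preset correlation, and so were 2 of 23 lists that had not been shifted. Simulated genes varied independently, with the same spread in every group. In the data, replicates differed most with control siRNA (chi-square per degree of freedom 4.5, against 2.91 and 1.83 in the other groups). The rates for single genes therefore need not hold for comparisons against control siRNA. The estimated correlation within lists reached 0.70 in the data (OXPHOS genes) and was 0.56 for interferon genes, so these rates do not carry over to the list calls.

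Alternatives were other pseudocounts (0.5 and 5), no filter, a minimum of 50, and upper-quartile, total and quantile scaling. Others were the replicate block, a fit of only the 2 groups compared, no mean-variance trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out. On the recovered reads, edgeR called 3263, 1336 and 2111 genes in the 3 comparisons. Comparisons that share libraries were set beside 100 draws of unchanged groups. Gene positions and 3' UTR sequences came from GENCODE M21, which is on the same build.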

Results

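Gene expression was measured in primary mouse adipocytes whose Ppargc1a gene is flanked by loxP sites. Ppargc1a encodes PGC-1alpha, a transcriptional coactivator of mitochondrial genes, and Rbm43 encodes an RNA-binding protein. Cells received adenovirus encoding GFP or the Cre recombinase, which excises loxP-flanked DNA, then control siRNA or Rbm43 siRNA, and were fully differentiated. Each of the 3 groups had 2 libraries, with 15775398 to 21961724 reads in genes per library. Spearman correlations across genes were 0.9965, 0.9976 and 0.998 within groups and 0.9915 to 0.9964 between groups. The first principal component (43.1% of variance) parted control siRNA from Rbm43 siRNA, and the second (19.5%) parted the GFP and Cre libraries with Rbm43 siRNA. Replicates differed by more than sampling noise in every group, most with control siRNA (chi-square per degree of freedom 4.5, against 2.91 and 1.83 in the groups with GFP and Cre virus and Rbm43 siRNA).

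The siRNA target and the floxed gene were examined first in each library. Rbm43 (mm10 chromosome 2, 51924448 to 51935163, minus strand) had normalized counts of 185 and 224 with control siRNA. It had 43.7 and 46.6 with Rbm43 siRNA and GFP virus, and 53.8 and 32.5 with Rbm43 siRNA and Cre virus. Its log2 fold change against control siRNA was −2.15 ± 0.21 with GFP virus (adjusted p = 3.59e-07) and −2.26 ± 0.21 with Cre virus (adjusted p = 4.35e-07). Ppargc1a (chromosome 5, 51454250 to 51567726, minus strand) rose from 183 ± 27.4 to 411 ± 16.6 with Rbm43 siRNA and GFP virus (SD, n = 2 each), a log2 fold change of 1.17 ± 0.10 (adjusted p = 7.68e-08). In the libraries labelled Cre virus its count was 466 ± 4.28 (SD, n = 2), with a log2 fold change of 0.18 ± 0.10 against GFP virus (adjusted p = 0.330). A count over the whole gene includes exons outside the excised part, so it does not check excision, and directions below follow the virus labels.

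**Figure D1:**
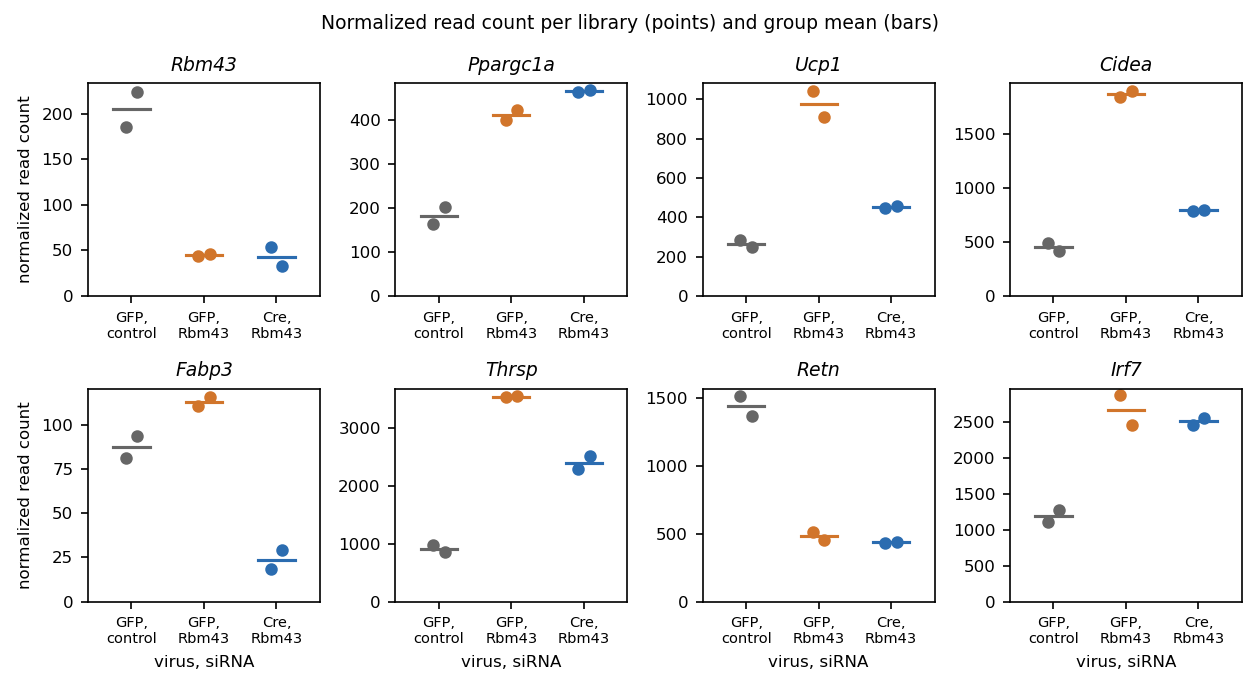
Normalized read count (vertical axis, from 0) of 8 genes in each library (points) with the group mean (horizontal bar), by virus and siRNA. Rbm43 lay at or below 53.8 in the 4 libraries with Rbm43 siRNA, against 185 and 224 with control siRNA, and Ppargc1a was 463 and 469 in the libraries labelled Cre virus.

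The first comparison asks what Rbm43 siRNA changed in cells with GFP virus. Genes of heat production and mitochondrial respiration rose. Ucp1, the uncoupling protein of brown fat, went from 266 ± 25.2 to 976 ± 95.0 normalized counts, and Cidea, a lipid droplet protein abundant in brown fat, from 452 ± 51.5 to 1864 ± 39.9 (SD, n = 2 each). Their log2 fold changes were 1.87 ± 0.09 and 2.05 ± 0.07 (limma adjusted p = 4.74e-11 and 5.92e-13). Of the 14211 genes tested, 3301 changed: 1914 rose and 1387 fell, and 139 rose and 45 fell by more than 2-fold.

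The nuclear genes of oxidative phosphorylation (OXPHOS) rose together: 71 of 76 rose and 0 fell, with 71 rising adjusted over the list alone, and the median log2 fold change was 0.45. Ndufb6 of complex I rose by 0.81, Sdhd of complex II by 0.71, the electron carrier Cycs by 0.66 and Cox5a of complex IV by 0.68. Camera called the list (adjusted p = 1.02e-45), with an adjusted p = 0.226 with an estimated correlation. Of 18 tricarboxylic acid cycle genes, 15 rose and 0 fell (15 adjusted over the list alone; median 0.47), Pdhb by 0.75, Dld by 0.60 and citrate synthase (Cs) by 0.58. Of 24 genes of fatty acid oxidation, 17 rose and 0 fell (19 adjusted over the list alone; median 0.33), among them Acaa2 and Ehhadh by 0.81 and Etfdh by 0.66. Both lists were called (adjusted p = 2.18e-16 and 4.93e-13), each with an adjusted p = 0.223 with an estimated correlation. Of the 13 mRNAs encoded by mitochondrial DNA, 10 rose and 0 fell (12 adjusted over the list alone; median 0.26), ND1 by 0.40 and ND6 by 0.38 (adjusted p = 1.63e-07, and adjusted p = 0.226 with an estimated correlation). These mRNAs took 5.31% and 5.56% of the counts with Rbm43 siRNA and GFP virus, and 4.32% to 4.56% in the other 4 libraries. Of 25 genes of mitochondrial biogenesis, 12 rose and 0 fell (12 adjusted over the list alone; median 0.13), with Ppargc1b, a paralog of Ppargc1a, up by 1.07 and the nuclear receptor Esrra by 0.62 (adjusted p = 3.04e-04, and adjusted p = 0.186 with an estimated correlation).

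Of 24 thermogenic genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.65). Letmd1 rose by 1.16 and glycerol kinase (Gk) by 1.00 beside Cidea and Ucp1, and the member that fell was the beta-3 adrenergic receptor Adrb3, at −0.69 (adjusted p = 4.62e-13, and adjusted p = 0.141 with an estimated correlation). Of 21 lipogenic genes, 17 rose and 0 fell (18 adjusted over the list alone; median 0.29). Thrsp, a regulator of lipogenesis, rose by 1.96, the transcription factor Mlxipl by 1.24 and the carboxylases Acacb and Acaca by 0.95 and 0.67 (adjusted p = 1.66e-15, and adjusted p = 0.226 with an estimated correlation). Mature adipocyte markers went both ways. Of 28, 16 rose and 7 fell (16 and 7 adjusted over the list alone; median 0.21), with Gpd1 up by 0.85 and Pparg by 0.64, while the adipokine resistin (Retn) fell by 1.56 and Adrb3 by 0.69 (adjusted p = 0.00159, and adjusted p = 0.536 with an estimated correlation). The adipocyte and thermogenic lists share 2 genes.

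Interferon-response genes also rose, 38 of 57 with 0 falling (46 adjusted over the list alone; median 0.40). The transcription factor Irf7 rose by 1.16, the nucleic acid sensor Zbp1 by 0.92 and the GTPase Gbp3 by 0.86 (adjusted p = 9.93e-18, and adjusted p = 0.311 with an estimated correlation). Without GFP virus, Rbm43 siRNA replicate 1, 25 members rose. Of 19 macrophage markers, 1 rose and 4 fell (3 and 4 adjusted over the list alone; median −0.03; adjusted p = 0.643), with Csf1r at −0.57 and Cd14 at −0.56.

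Groups that fell included the integrated stress and unfolded protein responses, with 23 of 30 genes down and 1 up (26 and 1 adjusted over the list alone; median −0.29). The chaperone Hspa5 fell by 0.42, Herpud1 by 0.54 and the pseudokinase Trib3 by 0.67, while the lipoprotein receptor Vldlr rose by 0.44 (adjusted p = 1.91e-12, and adjusted p = 0.141 with an estimated correlation). Of 36 extracellular matrix genes, 22 fell and 1 rose (25 and 2 adjusted over the list alone; median −0.23), Col15a1 by 0.75 and Tnc by 0.39 (adjusted p = 4.22e-09, and adjusted p = 0.255 with an estimated correlation). Of 49 cytosolic ribosomal proteins, 32 fell and 0 rose (35 falling adjusted over the list alone; median −0.17), Rps6 by 0.41 and Rps2 by 0.39 (adjusted p = 1.46e-13, and adjusted p = 0.304 with an estimated correlation). Reads of ribosomal protein genes can be shared with their many pseudogenes. Of 21 preadipocyte and fibroblast markers, 7 fell and 1 rose (8 and 2 adjusted over the list alone; median −0.10), Gsn by 0.42 and Vim by 0.33 (adjusted p = 0.00842, and adjusted p = 0.226 with an estimated correlation). This list was not called once genes with the 3' UTR heptamers of the closing section were left out (3 of 13 fell; median −0.08; adjusted p = 0.213).

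The 10 largest rises were led by the ceramidase Acer2, up by 2.20 from 495 ± 60.4 to 2268 ± 60.7 (SD, n = 2 each; adjusted p = 4.15e-13). Dnajc22 rose by 2.08, Gbp10 by 2.01, the phospholipid enzyme Cds1 by 1.81, the inositol phosphatase Impa2 by 1.62, the cannabinoid receptor Cnr1 by 1.46 and the carbonic anhydrase Car2 by 1.45, beside Cidea, Thrsp and Ucp1. Gbp10 belongs to a gene family whose near-identical members can split reads. Besides Rbm43, the largest falls were Aldh1a3, a retinaldehyde dehydrogenase, at −2.12, Nnat at −1.90, Retn at −1.56, Wfdc21 at −1.30, Cbr2 at −1.26 and Mmd2 at −1.25. Dio3, which inactivates thyroid hormone, fell by 1.04, the actin gene Actg1, which has close paralogs, by 1.04 and the matrix protein gene Cilp by 1.03. The count of changed genes was 2045 with DESeq2, 1304 with limma without the mean-variance trend and 2115 without GFP virus, Rbm43 siRNA replicate 2. It was 2560 with only the 2 groups compared. With upper-quartile scaling 1603 rose and 1861 fell, so the balance of rises and falls over all genes is not fixed by these data.

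**Figure D2:**
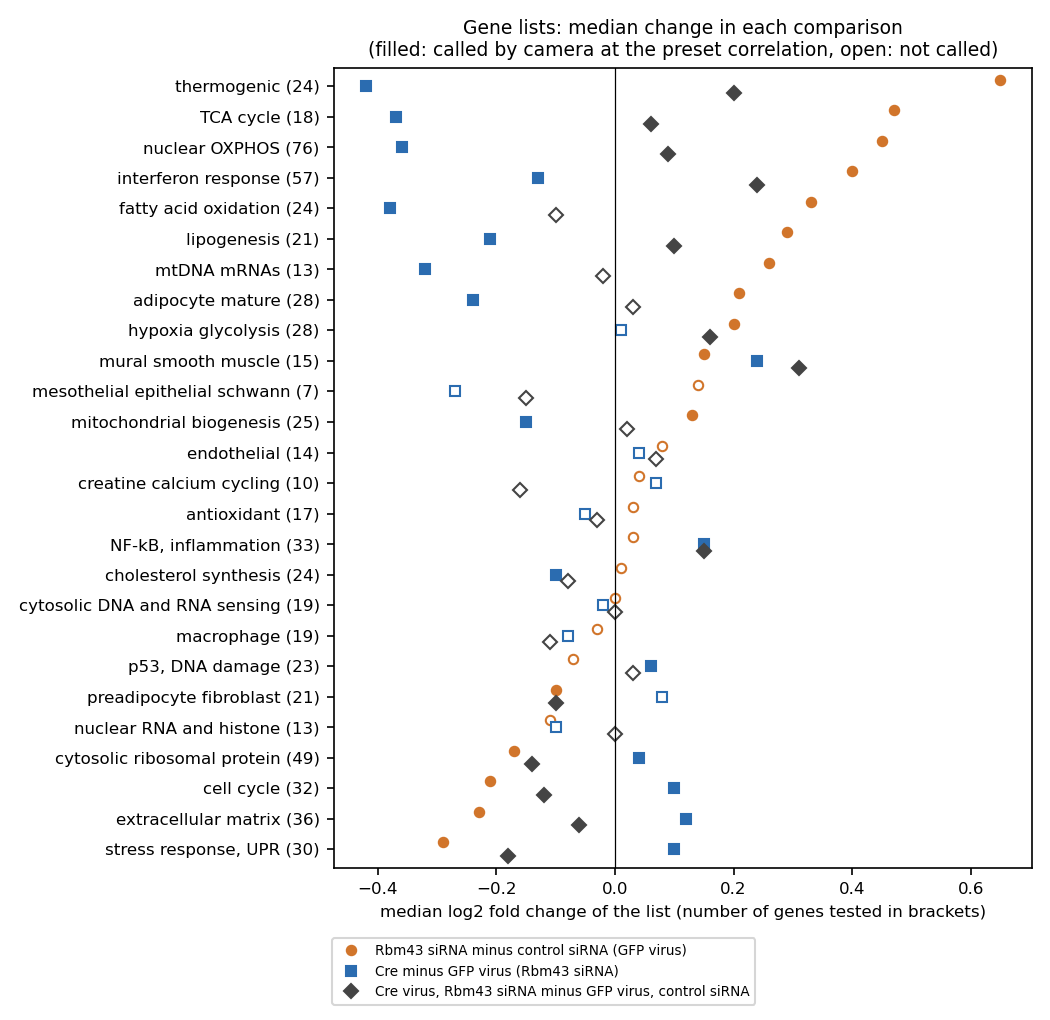
Median log2 fold change (horizontal axis) of 26 gene lists (genes tested in brackets) in the 3 comparisons; filled symbols mark lists called by camera at the preset correlation. The OXPHOS list had medians of 0.45 with Rbm43 siRNA, −0.36 with Cre virus and 0.09 for both against GFP virus with control siRNA.

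The second comparison asks what Cre virus, meant to excise Ppargc1a, changed in cells with Rbm43 siRNA. The genes of heat production and oxidative metabolism were lower in the libraries labelled Cre virus. Fabp3, the fatty acid carrier of heart and brown fat, fell from 113 ± 3.51 to 23.8 ± 7.35 normalized counts, Cidea from 1864 ± 39.9 to 791 ± 4.91 and Ucp1 from 976 ± 95.0 to 452 ± 9.90 (SD, n = 2 each). The log2 fold changes were −2.24 ± 0.21, −1.24 ± 0.07 and −1.10 ± 0.09 (limma adjusted p = 2.31e-06, 1.46e-08 and 5.49e-07). Of the 14211 genes, 1208 changed: 372 rose and 836 fell.

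In the OXPHOS list 69 of 76 genes fell and 0 rose (74 falling adjusted over the list alone; median −0.36), Cycs by 0.60, Uqcrfs1 and Uqcrc2 of complex III by 0.52 and 0.49 and Sdhd by 0.51 (adjusted p = 7.16e-66, and adjusted p = 0.226 with an estimated correlation). Without Cre virus, Rbm43 siRNA replicate 1, 44 fell. Of 24 fatty acid oxidation genes 20 fell and 0 rose (20 adjusted over the list alone; median −0.38), Acaa2 by 0.67 and Hadhb by 0.50, and of 24 thermogenic genes 16 fell and 0 rose (17 adjusted over the list alone; median −0.42). The nuclear receptor Ppara fell by 0.95 and Cox7a1 by 0.79. These lists were called (adjusted p = 7.29e-31 and 8.28e-18), each with an adjusted p = 0.141 with an estimated correlation, and 10 thermogenic genes fell without Cre virus, Rbm43 siRNA replicate 2. Of 18 tricarboxylic acid cycle genes 17 fell and 0 rose (17 adjusted over the list alone; median −0.37), Sucla2 by 0.50 (adjusted p = 3.26e-27, and adjusted p = 0.171 with an estimated correlation). Of the 13 mitochondrially encoded mRNAs 11 fell and 0 rose (12 adjusted over the list alone; median −0.32), ND1 by 0.40 (adjusted p = 2.21e-12, and adjusted p = 0.223 with an estimated correlation). Of 25 genes of mitochondrial biogenesis 9 fell and 0 rose (12 adjusted over the list alone; median −0.15), Ppargc1b by 0.48 and Esrra by 0.46 (adjusted p = 6.07e-08, and adjusted p = 0.141 with an estimated correlation).

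Mature adipocyte markers were lower too: 17 of 28 fell and 0 rose (23 falling adjusted over the list alone; median −0.24). The glucose transporter Slc2a4 fell by 0.59, Rbp4 by 0.57, Pparg by 0.37 and adiponectin (Adipoq) by 0.32 (adjusted p = 1.79e-18, and adjusted p = 0.223 with an estimated correlation). The number falling was 11 without GFP virus, Rbm43 siRNA replicate 2, and 8 and 9 without replicates 1 and 2 of Cre virus with Rbm43 siRNA. Of 21 lipogenic genes 11 fell and 0 rose (14 adjusted over the list alone; median −0.21), Thrsp by 0.56 and Acacb by 0.44 (adjusted p = 1.84e-12, and adjusted p = 0.226 with an estimated correlation). Of 57 interferon-response genes 7 fell and 0 rose (12 adjusted over the list alone; median −0.13), Rsad2 by 0.59 (adjusted p = 6.99e-07, and adjusted p = 0.564 with an estimated correlation).

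Some contractile and matrix genes rose. Of 15 mural and smooth muscle markers 8 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.24), Des by 0.49, Lmod1 by 0.37 and Tagln by 0.29 (adjusted p = 1.35e-06, and adjusted p = 0.226 with an estimated correlation). The number rising was 2 without GFP virus, Rbm43 siRNA replicate 2, and 3 and 1 without replicates 1 and 2 of Cre virus with Rbm43 siRNA. Of 36 extracellular matrix genes 10 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.12), Ctgf by 0.57 (adjusted p = 6.41e-09, and adjusted p = 0.255 with an estimated correlation). Of 33 inflammatory NF-kB targets 4 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.15), with the cyclooxygenase Ptgs2 up by 1.06 and Sod2 at −0.40 (adjusted p = 7.13e-06, and adjusted p = 0.226 with an estimated correlation). Of 30 stress-response genes 2 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.10; adjusted p = 1.41e-04, and adjusted p = 0.171 with an estimated correlation).

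Ptgs2 was the largest rise, from 541 ± 80.0 to 1126 ± 83.4 (SD, n = 2 each). Nipal1 rose by 0.84, the nuclear receptors Nr4a1 and Vdr by 0.76 and 0.64, the calcium channel gene Cacna1d by 0.74, the alkaline phosphatase Alpl by 0.71 and the chemokine Cxcl14 by 0.69. Fchsd1, Arid5a and the elastase Mmp12 rose by 0.63, 0.62 and 0.62. Besides Fabp3, Cidea, Ucp1 and Ppara, the largest falls were Dnajc22 at −1.07, Ntrk3 at −0.89, S100b at −0.86, Mmd2 at −0.85, Dnajb13 at −0.81 and Impa2 at −0.79. The count of changed genes varied with the libraries and settings used: 2060 and 2068 without replicates 1 and 2 of GFP virus with control siRNA, 468 without GFP virus, Rbm43 siRNA replicate 2, 312 and 329 without replicates 1 and 2 of Cre virus with Rbm43 siRNA, 2083 with only the 2 groups compared, and 609 with no filter. Limma without the mean-variance trend called 0, with 2355 genes at an unadjusted p under 0.05 (DESeq2 called 826 and edgeR 1336), and total scaling gave 565 rises and 734 falls.

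The first comparison and the second share the libraries with GFP virus and Rbm43 siRNA, with opposite sign. Of the 1914 genes that rose with Rbm43 siRNA, 619 fell with Cre virus, 74.0% of all that fell there, where independent lists would share 112.6. Another 163 fell with Rbm43 siRNA and rose with Cre virus (36.3 for independent lists), while 23 rose in both and 21 fell in both. The 619 genes had median log2 fold changes of 0.42 and −0.34, and of 0.09 for Cre virus and Rbm43 siRNA against GFP virus and control siRNA, where 177 were still higher and 15 lower. Across genes, which are not independent replicates, the correlation was −0.461, and unchanged groups sharing those libraries gave −0.498 in 100 simulated draws. The covariance was −0.0374 against −0.0165 simulated, a difference of −0.0209, and −0.0172 and −0.0226 when 1 shared library was used for each comparison. Part of the overlap may still come from the shared libraries, and it was 317 without GFP virus, Rbm43 siRNA replicate 2, and 215 and 235 without replicates 1 and 2 of Cre virus with Rbm43 siRNA.

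**Figure D3:**
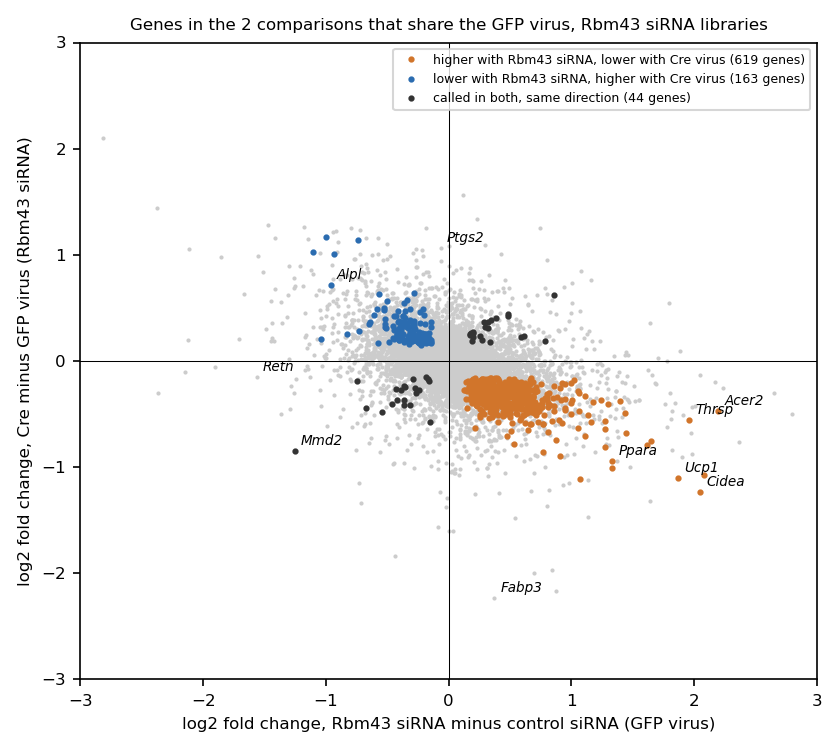
Log2 fold change with Cre virus (vertical axis) against that with Rbm43 siRNA (horizontal axis), 1 point per gene, with genes called in both comparisons coloured by direction and 6 genes outside the axes. The 619 genes higher with Rbm43 siRNA and lower with Cre virus lie at the lower right, Cidea at 2.05 and −1.24 among them; the shared libraries alone tilt the cloud this way.

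The third comparison sets Cre virus with Rbm43 siRNA against GFP virus with control siRNA, which differ in both treatments. Rbm43 was lower and Ppargc1a higher (1.35 ± 0.10 on the log2 scale, adjusted p = 2.67e-08) in the libraries labelled Cre virus. Acer2 rose from 495 ± 60.4 to 1635 ± 128 and Irf7 from 1187 ± 118 to 2505 ± 74.1, while Retn fell from 1439 ± 105 to 436 ± 4.62 (SD, n = 2 each). Their log2 fold changes were 1.72 ± 0.08, 1.08 ± 0.07 and −1.72 ± 0.08 (limma adjusted p = 4.26e-11, 7.78e-09 and 4.26e-11). Of the 14211 genes, 2096 changed: 1203 rose and 893 fell.

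Interferon-response genes were also higher here: 28 of 57 rose and 2 fell (33 and 2 adjusted over the list alone). Their median was 0.24, against 0.40 in the first comparison. Zbp1 rose by 0.89, Gbp3 by 0.62 and Bst2 by 0.56. Camera called the list (adjusted p = 2.75e-11, and adjusted p = 0.435 with an estimated correlation). The number rising was 15 and 14 without replicates 1 and 2 of Cre virus with Rbm43 siRNA. Of 15 mural and smooth muscle markers 9 rose and 0 fell (10 adjusted over the list alone; median 0.31), Myh11 by 0.85, Cnn1 by 0.61 and Acta2 by 0.44 (adjusted p = 1.35e-08, and adjusted p = 0.223 with an estimated correlation). Of 33 inflammatory genes 12 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.15), Ptgs2 by 1.00, Saa3 by 0.93 and Lcn2 by 0.79 (adjusted p = 2.43e-05, and adjusted p = 0.226 with an estimated correlation). The OXPHOS list had 21 of 76 genes up and 4 down (25 and 4 adjusted over the list alone; median 0.09), with Ndufb6 and Ndufc1 up by 0.37 and 0.51 and Ndufa10 and Ndufb3 down by 0.35 and 0.31 (adjusted p = 1.37e-05, and adjusted p = 0.653 with an estimated correlation). Its rises numbered 45 and 9 without replicates 1 and 2 of GFP virus with control siRNA, and 5 without either replicate of Cre virus with Rbm43 siRNA.

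Of 24 thermogenic genes 10 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.20), Cidea by 0.81, Ucp1 by 0.77 and Letmd1 by 0.58, with Adrb3 at −0.77 (adjusted p = 6.91e-04, and adjusted p = 0.226 with an estimated correlation). Of 21 lipogenic genes 8 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.10), Thrsp by 1.40 and Fasn by 0.61 (adjusted p = 1.63e-07, and adjusted p = 0.310 with an estimated correlation). Mature adipocyte markers again went both ways, 7 of 28 up and 9 down (9 and 9 adjusted over the list alone), with Rbp4 at −0.72 and Cebpa at −0.60. The list was not called (adjusted p = 0.164), and its median (0.03) and test differ in sign. Of 30 stress-response genes 12 fell and 1 rose (16 and 1 adjusted over the list alone; median −0.18), Sdf2l1 by 0.71 and Herpud1 by 0.44 (adjusted p = 9.22e-09, and adjusted p = 0.141 with an estimated correlation). Of 49 cytosolic ribosomal proteins 20 fell and 0 rose (30 adjusted over the list alone; median −0.14), Rps6 by 0.32 and Rpl13 by 0.29 (adjusted p = 1.02e-12, and adjusted p = 0.310 with an estimated correlation), numbering 37 without GFP virus, control siRNA replicate 2, and 5 and 9 without replicates 1 and 2 of Cre virus with Rbm43 siRNA. Of the other mitochondrial lists, fatty acid oxidation had 4 of 24 genes up and 8 down (5 and 9 adjusted over the list alone; adjusted p = 0.120), and the mitochondrially encoded mRNAs 2 of 13 up and 0 down (2 adjusted over the list alone; adjusted p = 0.905). The tricarboxylic acid cycle had 5 of 18 genes up and 2 down (5 and 2 adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.588 with an estimated correlation).

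After Acer2, the largest rises were Gbp10 at 1.58, Ifi27l2b at 1.55, Cnr1 at 1.52, Mmp12 at 1.47, Thrsp at 1.40, Celsr3 at 1.36, Ppargc1a at 1.35, the cytochrome P450 gene Cyp2f2 at 1.29 and Cds1 at 1.27. Ifi27l2b, like Gbp10, has close paralogs. After Rbm43, the largest falls were Mmd2 at −2.11, Nnat at −1.95, Aldh1a3 at −1.93, Fabp3 at −1.86, Retn at −1.72, Cbr2 at −1.56, Wfdc21 at −1.28, the sialyltransferase St3gal6 at −1.15 and Hacl1, an enzyme of peroxisomal alpha-oxidation, at −1.11. With upper-quartile scaling 1006 rose and 1085 fell. The count of changed genes was 1251 with no filter, 433 without the mean-variance trend, 1229 with DESeq2, and 770 and 827 without replicates 1 and 2 of Cre virus with Rbm43 siRNA.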

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

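The tests with genes carrying a heptamer site left out, and those on the counts of list members, were chosen after seeing the data; the rest were planned. Gene counts in the comparisons of Rbm43 siRNA, of Cre virus, and of both treatments were 3301, 1208 and 2096. Without the mean-variance trend they were 1304, 0 and 433 (2355 genes at an unadjusted p under 0.05 for the 0), and the genes higher with Rbm43 siRNA and lower with Cre virus went from 619 to 0; the cause was not tested. DESeq2 called 2045 and 1229 in the first comparison and the third comparison. With no filter on low values, which tests 22944 genes, the counts in the second comparison and the third comparison were 609 and 1251, and 380 genes were higher with Rbm43 siRNA and lower with Cre virus. With only the 2 groups compared the counts were 2560, 2083 and 1968, and 77.5% of the 3301 calls of the first comparison were kept. The second spread is then without the control libraries, whose replicates differed most (chi-square per degree of freedom 4.5, against 2.91 and 1.83). A spread shared by all groups may thus be too small for comparisons against control siRNA. Leaving out 1 library at a time gave 2115 to 3633, 312 to 2068 and 770 to 2654 genes, and 215 to 868 higher with Rbm43 siRNA and lower with Cre virus; a lone library is then assumed to vary like the other groups.

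The same range for list members was 25 to 52 rising interferon genes in the first comparison, 44 to 74 falling OXPHOS, 10 to 16 thermogenic and 8 to 22 adipocyte genes and 1 to 8 rising mural genes in the second. In the third comparison it was 5 to 45 rising OXPHOS genes, 14 to 38 rising interferon genes and 5 to 37 falling ribosomal proteins. Without the trend, rising fatty acid oxidation genes numbered 10 and interferon genes 14, and falling stress-response and matrix genes 10 and 5, in the first comparison. In the second, falling OXPHOS, fatty acid oxidation, thermogenic and adipocyte genes and rising mural genes each numbered 0. In the third comparison, rising OXPHOS, interferon and mural genes numbered 0, 6 and 3 and falling ribosomal proteins 0. With no filter, rising mural genes in the second comparison numbered 4, and in the third comparison rising OXPHOS genes 7, interferon genes 16 and falling ribosomal proteins 13. The cause was not tested.

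The lists called by camera numbered 16, 17 and 13, and 0 in each comparison with an estimated correlation (smallest adjusted p 0.141). With fry, 12, 13 and 8 lists were called. The OXPHOS list was called in the first and second comparisons (fry adjusted p = 0.017 and 0.0235) and not in the third (0.346). Fatty acid oxidation and thermogenic genes were called in the first and second (0.00302 each). Interferon genes were called in none (0.055, 0.346 and 0.13), and mature adipocyte markers not in the first (0.0902). With genes that carry a heptamer site left out, 2486 of 11570 genes changed in the first comparison, and 14, 16 and 10 lists were called. The calls that ended were those of preadipocyte (adjusted p = 0.213, median from −0.10 to −0.08) and mural markers (0.184, median from 0.15 to 0.13) in the first comparison and ribosomal proteins (0.0612, median from 0.04 to 0.03) in the second. In the third comparison they were those of preadipocyte (0.351, median from −0.10 to −0.03), matrix (0.125, median from −0.06 to −0.03) and cell cycle genes (0.0554, median −0.12 in both), each with fewer members tested. Libraries with the same replicate number showed no shared deviation: deviations from the group means correlated at 0.019, −0.042 and −0.037 between groups. The labels do not say whether a number marks a shared culture, animal or day, and these values cannot settle it. With the replicate block the gene counts were 3412, 1304 and 2214. Upper-quartile, total and quantile scaling moved the median of all genes at most to −0.042 on the log2 scale, gave 1603 rises and 1861 falls (upper-quartile, first comparison), 1006 and 1085 (upper-quartile, both treatments) and 565 and 734 (total, second), and kept at least 88.9% of calls with 0 reversed.

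Of 6733 recomputed log2 fold changes of 377 named gene results, 6214 kept direction and side of the threshold, 445 were no longer called, 67 became called and 7 changed sign. None of the 7 had been called: Rbm43 in the second comparison (range without 1 library −0.46 to 0.25), Acta1 in the first (−0.06 to 0.16, and −0.01 without control siRNA replicate 2), and in the second Eng (−0.02 to 0.34), Il7r (−0.24 to 0.45) and Actn3 (−0.03 to 0.28), each without 1 library, and ND4 in the third comparison (0.01, quantile scaling). Without 1 library, the Rbm43 fold change against control siRNA ranged from −2.29 to −2.01 with GFP virus and from −2.61 to −1.90 with Cre virus, and that of Ppargc1a from 1.02 to 1.32 and from 1.20 to 1.51. The correlation of the 2 effects then ranged from −0.558 to −0.407. Depth limits low genes: in the library with 15775398 reads, 3 reads are worth 3.65 normalized counts.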

Other observations

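The tests on single library pairs, macrophages, scaling and mature adipocytes were chosen after the results were seen; the tests on heptamers and on 1 control library were written down before their results were seen, though the list results and the levels of an interferon gene, Ifit1, in each library had been viewed. The other fixed lists follow, and some changed as much as lists described above. Of 28 genes of hypoxia and glycolysis, 17 rose and 2 fell with Rbm43 siRNA (18 and 3 adjusted over the list alone; median 0.20), Hk2 by 0.55 and Egln3 by 0.53 (camera adjusted p = 5.74e-06, and adjusted p = 0.472 with an estimated correlation). Of these, 4 rose and 3 fell with Cre virus (6 and 5 adjusted over the list alone; adjusted p = 0.791), and 14 rose and 1 fell in the third comparison (16 and 1; median 0.16; adjusted p = 2.45e-08, and adjusted p = 0.359 with an estimated correlation). Of 32 cell cycle genes, 6 fell and 1 rose with Rbm43 siRNA (6 and 1 adjusted over the list alone; median −0.21), Top2a by 0.30 and Mcm6 by 0.37 (adjusted p = 1.25e-04, and adjusted p = 0.171 with an estimated correlation). With Cre virus 1 rose (0 adjusted over the list alone; median 0.10; adjusted p = 0.00641, and adjusted p = 0.223 with an estimated correlation), Rrm2. Of 17 antioxidant genes, 4 rose and 5 fell with Rbm43 siRNA and 1 rose and 5 fell with Cre virus (adjusted p = 0.732 and 0.0890). The peroxiredoxin of mitochondria, Prdx3, fell by 0.54 and again by 0.49, and by 1.03 in the third comparison.

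Of 23 p53 targets, 5 fell and 1 rose with Rbm43 siRNA (adjusted p = 0.0906), and 4 rose and 0 fell with Cre virus (adjusted p = 0.00526, and adjusted p = 0.226 with an estimated correlation), Plk2 by 0.47 and Cdkn1a by 0.23. Of 24 cholesterol synthesis genes, 5 rose and 1 fell with Rbm43 siRNA (adjusted p = 0.487), and 0 rose and 4 fell with Cre virus (median −0.10; adjusted p = 2.12e-04, and adjusted p = 0.359 with an estimated correlation). Among 10 genes of creatine and calcium cycling, 0 rose and 2 fell with Rbm43 siRNA (adjusted p = 0.724), Alpl at −0.96 and Gatm at −0.94, and Alpl rose by 0.71 with Cre virus while Atp2a3 fell by 0.76 (adjusted p = 0.538). Of 19 sensors of cytosolic DNA and RNA, 2 rose and 1 fell with Rbm43 siRNA (adjusted p = 0.463), Nlrc5 by 0.59, and 0 rose and 1 fell with Cre virus (adjusted p = 0.790). Of 13 nuclear RNA and histone genes used as signs of RNA quality, 3 rose and 4 fell with Rbm43 siRNA and 3 rose and 2 fell with Cre virus (adjusted p = 0.745 and 0.790). Of 14 endothelial markers, 0 rose and 1 fell with Rbm43 siRNA and none was called with Cre virus (adjusted p = 0.981 and 0.325), and of 7 mesothelial, epithelial and Schwann cell markers 1 rose with Rbm43 siRNA and 1 fell with Cre virus, both S100b (adjusted p = 0.724 and 0.0906). Inflammatory NF-kB targets numbered 6 up and 2 down of 33 with Rbm43 siRNA (adjusted p = 0.693), mural markers 4 up of 15 (adjusted p = 0.0320, and adjusted p = 0.479 with an estimated correlation). Of the skeletal muscle list, Acta1 rose by 0.57 with Cre virus, and of the lymphocyte and mast cell list Kit and Il7r had log2 fold changes of 1.10 and 0.10 there (adjusted p = 0.0671 and 0.925).

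Genes that were lower in both Rbm43 siRNA groups than with control siRNA more often carried 1 of 2 overlapping heptamers in their 3' UTRs, 199 of 550 (36.2%) against 20.1% of genes called in neither comparison; the heptamers were picked on these same fold changes, so the excess is no separate support. Of 16150 heptamers tested in the 3' UTRs of 12533 genes (linear model with UTR length, GC content and mean expression), CCTTGAA had the lowest t (−10.57), with a shift of −0.080 ± 0.0075 (SE) on the log2 scale over 1930 genes (Bonferroni p = 6.92e-22; permutation p = 0.001, the smallest that the permutations over genes can give), and ACCTTGA the next (−8.43), with −0.071 over 1425 genes; genes are not independent replicates. Both lie in the 3' UTR of Rbm43 itself, at positions 157 to 164 (mm10 chromosome 2, 51925012 to 51925019, minus strand). Their shifts between the 2 groups with Rbm43 siRNA were 0.003 and −0.001. Seed-type off-target repression by the Rbm43 siRNA is thus a candidate explanation for part of these falls. Of the 9 largest named falls besides Rbm43, Aldh1a3 and Actg1 carry a site and Nnat, Retn, Wfdc21, Cbr2, Mmd2, Dio3 and Cilp do not. Sites are not clearly in excess among these 9, as 20.1% of genes called in neither comparison carry one. A single library does not set the shift of CCTTGAA, since it was −0.074 or lower in each of the 8 pairs of an Rbm43 siRNA library and a control library, and 0.005 between the 2 control libraries. The siRNA sequence was not used here, and 11.6% of the heptamers occur somewhere in the Rbm43 mRNA. Among the 4 lower heptamers past Bonferroni, 1 does not occur there (GCCTTGA, −0.039, permutation p = 0.006), although it shares the bases CCTTGA with CCTTGAA and ACCTTGA. Binding of Rbm43 protein to such sites stays open and untested. So does a seed of the control siRNA for GATTAAC, which had the highest t (shift 0.087 over 549 genes).

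Of 57 interferon-response genes, 38 rose in the Rbm43 siRNA group with GFP virus and 28 in that with Cre virus. With GFP virus the direction of the list did not rest on 1 control library. Its median went from 0.40 to 0.24 without control siRNA replicate 1 and to 0.52 without replicate 2. The planned count was of the 38 still called, and its lower value was 27, without replicate 1. That count rests on 1 control library, and the members vary together (estimated correlation 0.56). It therefore cannot exclude variation between the control libraries as a source of part of the rises. With Cre virus fewer list members were called higher without control siRNA replicate 1, or without either replicate of Cre virus with Rbm43 siRNA. More were called without control siRNA replicate 2. These counts cover the whole list and do not follow the 28. A higher share of macrophages as the whole cause would raise their markers alike, and of 19 that passed the filter 1 rose and 4 fell (median −0.03), Csf1r by 0.57; the 4 most abundant went both ways, Lyz2 at −0.12 ± 0.08, Mpeg1 at 0.24 ± 0.09, Ctss at 0.33 ± 0.12 and Adgre1 at 0.06 ± 0.11 (adjusted p = 0.349, 0.0694, 0.0475 and 0.756). The control libraries received an siRNA as well, so a response to siRNA in general is shared by the groups. A response particular to the Rbm43 siRNA duplex, and an effect of lower Rbm43, both go with the siRNA label in this design. No test here parts them.

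OXPHOS genes were higher with Rbm43 siRNA and lower with Cre virus. Under 3 other scalings the median of the list with Rbm43 siRNA was at least 0.41 and that with Cre virus at most −0.33. These scalings moved the median of all genes at most to −0.042. Moves that small could not have removed the shift of the list. The values show only that the choice among these scalings does not set it. A higher share of mature adipocytes with Rbm43 siRNA would by itself raise their markers alike, and 7 fell, among them Retn by 1.56, Cfd by 0.38 and Cebpa by 0.36. A share alone thus does not explain all the marker changes. Whether it raised the OXPHOS genes cannot be decided, since those 7 could also have changed within the cells. Of 28 markers 16 rose (median 0.21, camera adjusted p = 0.00159, and adjusted p = 0.536 with an estimated correlation). Preadipocyte genes fell in 7 of 21 cases and matrix genes in 22 of 36. For the fall with Cre virus, fewer mature adipocytes cannot be told apart from a change within them, since the markers' median was −0.24 with 0 rising, while of the other cell types mural markers went with it (8 of 15 rose, 0 fell; median 0.24; adjusted p = 1.35e-06, and adjusted p = 0.226 with an estimated correlation; 1 to 8 rising without 1 library) and preadipocyte, endothelial and macrophage markers had medians of 0.08, 0.04 and −0.08 with 0 called. Excision of Ppargc1a is the explanation the design names, and it stays untested, since a whole-gene count includes exons outside the excised part. All the cells carried loxP-flanked Ppargc1a, so an effect of Cre virus itself cannot be told apart from one of excision. Cre virus was compared only in cells with Rbm43 siRNA, so whether the fall depends on Rbm43 siRNA cannot be asked here.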
